A study of Rattus norvegicus with 96 samples.

How the data were processed

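RNA was measured with Affymetrix rat expression arrays in tissue of alcohol-preferring (P) rats, from the central nucleus of the amygdala (CeA) and the shell of the nucleus accumbens (NAc shell). Per the labels, RNA was extracted with Trizol and an RNeasy kit and amplified in 2 cycles for labelling, starting with 25 ng. The deposited table holds log2 values, 1 column per array, that the authors made by RMA (background correction, quantile normalization and median polish per probe set). The RMA version, the scanner settings, the scan dates and any filter by the authors are not stated, and no raw intensity files were used. All 96 columns belonged to a labelled array, and no array was duplicated. Array medians overlapped between the regions, while lower quartiles (5.75 to 5.88 in the CeA, 6.01 to 6.16 in the NAc shell) and minima did not, so the regions look to have been normalized separately.

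The table held 31099 probe sets. The 57 control probe sets were left out of the tests, which left 31042. Of these, 20826 carried 1 gene symbol, 436 several, and 9780 were not listed in the annotation. Symbols of 20758 probe sets were looked up by Entrez ID, and probe sets without a symbol are given by their identifier. Genome positions were not used here. In each region, probe sets with a mean log2 value above the 40th percentile were tested: 18625, with a limit of 6.96 in the CeA and 7.09 in the NAc shell.

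Each region was fitted on its own with limma 3.58.1 in R 4.3.3, with a mean for each of the 6 groups of treatment and time, moderated variances with a trend on intensity, and Benjamini-Hochberg adjustment over the probe sets tested. Adjusted p under 0.05 counts as passing. Group comparisons were ethanol against water over the mean of the 3 times, ethanol against water at each time, the ethanol by time interaction, and time within each treatment (6 h and 24 h against 1 h, tested together). A fit of both regions tested the difference of the ethanol effects between regions, and the regions against each other in water rats. It treats the arrays of both regions as independent, since the labels do not say whether they came from the same rats.

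Gene lists for neural signalling, metabolism, stress responses, immunity and cell types were written from textbook knowledge. Of these 26 lists, 24 had at least 3 measured members and were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera compares a list with other genes. Fry tests whether a list's genes move, on balance, in 1 direction, and compares it with no other gene. Where a gene had several probe sets, a list used the one with the highest mean value. Beside the count over all genes, members are also counted with p values adjusted over the list alone. Those p values are not adjusted over the lists, regions and comparisons searched, so some members can pass in this way by chance.

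Genes named in the text followed a rule. For ethanol over the 3 times, the rule took the 8 passing genes with the largest change in each direction. It took 4 in each direction at a single time, 6 in each direction between regions, and the 8 smallest p values for interactions and time courses. Where no gene passed, the 4 smallest p values are named and said not to pass. Members of a list were named by their smallest p values, up to 4 per list. The groups, the lists, this rule and the other settings not described as added were fixed before the data were examined.

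Other settings tried were no filter, a filter at the 60th percentile, repeated quantile normalization, array quality weights, the difference between the 3 prime and 5 prime Gapdh control probe sets as a covariate for RNA integrity, and each array left out in turn. They also included a block for the number in the array title, a block for runs of title numbers in the CeA, and an adjusted p of 0.10 for ethanol over the 3 times. Added after the data were seen were that threshold for the other counts, the run block with other settings, the fit within each run, the time course averaged over treatments, cell-type marker means as covariates, a list of interferon-regulated genes, and a fit without arrays whose median correlation with the others of their region was more than 3 scaled median absolute deviations low. Group labels were also redrawn 100 times, the real labels included.

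The test was checked on simulated data in the same layout, with noise drawn independently for each probe set and array. The real arrays share variation, which apart from the batch shift below was not simulated, so these values may not hold for them. At a log2 change of 0.50, it recovered 86% of 50 changed probe sets in the CeA and 92% in the NAc shell. At 0.25 these shares were 42% and 58%. Of 18425 unchanged probe sets, 8 were called in the CeA and 7 in the NAc shell. With a simulated batch shift the CeA recovery at 0.50 was 40%, and 86% with the run block. The number of arrays limits the precision of each value.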

Results

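The series held 96 arrays of P rats, a line bred for high alcohol intake, 48 from each of 2 brain regions. The CeA is an output nucleus of the amygdala with a part in fear, stress and drug withdrawal, and the NAc shell is a striatal region of the reward system. Per the labels, ethanol rats had limited access to ethanol, described in the series title as binge drinking, and water rats had none. Tissue was taken 1, 6 or 24 h after the last session. The CeA had 11, 10 and 10 ethanol arrays and 6, 5 and 6 water arrays at these times, and the NAc shell had 10, 10 and 11 ethanol arrays and 7, 5 and 5 water arrays. Each region thus had 31 ethanol and 17 water arrays.

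Log2 values lay between 3.39 and 15.3 in the CeA and between 3.84 and 15.8 in the NAc shell. Array medians were 7.68 to 7.82 in the CeA and 7.78 to 7.85 in the NAc shell, and lower quartiles were 5.75 to 5.88 and 6.01 to 6.16. The regions look to have been normalized separately, so small differences in level between them carry that offset. The Gapdh control probe sets, which read both ends of 1 transcript, differed by 2.91 log2 (SD 0.53, n = 48) in the CeA and by 1.81 (SD 0.25, n = 48) in the NAc shell. Within times, this 3 prime minus 5 prime difference was 0.01 higher in ethanol than in water rats in the CeA (permutation p = 0.959, adjusted over 4 tests 0.959) and changed by -0.07 in the NAc shell (permutation p = 0.308, adjusted 0.411). For beta-actin the values were 0.10 in the CeA and 0.11 in the NAc shell, with an adjusted permutation p of 0.280 for each.

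The title numbers of the CeA arrays fell into 4 runs, within each of which the order of times restarted. The runs held 5, 10, 10 and 6 ethanol arrays and 3, 6, 6 and 2 water arrays. Mean Gapdh end differences in runs 1 to 4 were 2.46, 2.51, 3.45 and 3.09. Once group means were removed, ethanol and water arrays of 1 run had a mean correlation of 0.209, against -0.08 for arrays of different runs. The permutation p of this difference was 1e-04, the smallest that 9999 permutations can give, so CeA results are also given with runs as a block in the fit. The runs follow from the titles, but the prominence of this block in the text rests on the correlation seen in the data. By their median correlation with the other arrays, which was 0.950 to 0.985 in the CeA and 0.962 to 0.989 in the NAc shell, 4 CeA arrays and 5 NAc shell arrays stood low. The 4 CeA arrays were all in run 4. They included its only 2 water arrays, both at 6 h, and 1 of its 2 ethanol arrays at 6 h, while its other 4 ethanol arrays were at 1 h and 24 h. Ethanol and water are therefore compared within run 4 at 6 h alone, and counts against the water mean of a run set all 6 of its ethanol arrays against these 2.

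Ethanol drinkers and water drinkers of the CeA were compared over the mean of the 3 times (31 against 17 arrays), which asks what drinking leaves in this nucleus irrespective of the hour. Without a run block 0 probe sets passed, so the genes named first rest on the fit with runs as a block. In that fit the probe set 1368691_at of Gria3, a subunit of AMPA glutamate receptors, was higher in ethanol rats by 0.59 ± 0.11 log2 (SE, adjusted p = 0.0102). The other probe set of Gria3 read 0.02. For 1368691_at, 29 of 31 ethanol arrays lay above the water mean of their run. Khsrp (1376525_at), an RNA-binding protein of splicing and mRNA decay, was higher by 0.56 ± 0.10 (adjusted p = 0.00956, 27 of 31 arrays). Such counts of arrays, here and below, describe genes chosen on these same arrays and add no support of their own. Also higher were 3 single neuronal genes, the kinesin Kif1a (1384133_at) by 0.64 ± 0.14, the neuronal calcium sensor Hpcal4 (1375765_at) by 0.68 ± 0.16, and the synaptotagmin Syt10 (1370718_at) by 0.59 ± 0.14. Lower were Rtp4 (1379285_at), an interferon-induced gene, by -0.39 ± 0.09, Kcnip4 (1383220_at), which encodes a potassium channel-interacting protein, by -0.25 ± 0.06, and Adgra2 (1373599_at), an adhesion receptor of brain vessels, by -0.25 ± 0.06.

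Without the run block, limma passed 0 of 18625 probe sets, with 1519 at an unadjusted p under 0.05 (859 higher, 660 lower in ethanol rats). The 4 named genes with the smallest p values did not pass: Khsrp at 0.56 ± 0.11 (adjusted p = 0.0767), Rpap3 (1376853_at) at 0.44 ± 0.10, Akap8l (1375813_at) at 0.41 ± 0.09, and Herc1 (1394746_at) at 0.44 ± 0.10 (adjusted p = 0.190 each). With the block, 48 probe sets passed, 43 higher and 5 lower, and 3175 had an unadjusted p under 0.05. Adjusted p values of the other genes just named were 0.0281 for Kif1a, 0.0495 for Hpcal4, 0.0467 for Syt10, 0.0495 for Rtp4, 0.0349 for Kcnip4 and 0.0495 for Adgra2. Kif1a, Syt10, Hpcal4, Rtp4, Kcnip4 and Adgra2 showed their direction in 29, 30, 25, 29, 28 and 27 of the 31 ethanol arrays. Eif3a (1379485_at), a subunit of a translation initiation factor, was higher by 0.67 ± 0.14 (adjusted p = 0.0292, 27 of 31 arrays), Zrsr2-ps1 (1389874_at) by 0.51 ± 0.12 (adjusted p = 0.0494, 26 of 31) and Ubxn4 (1381542_at), of endoplasmic reticulum-associated degradation, by 0.48 ± 0.11 (adjusted p = 0.0467, 29 of 31). The smallest adjusted p belonged to a probe set without a gene name, 1391217_at, at 0.39 ± 0.06 (adjusted p = 0.00611).

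Other probe sets of the same genes moved little. The 24 called genes with a symbol included 17 with a further tested probe set. Of these 24 further probe sets, 20 had the same sign, 6 had an unadjusted p under 0.05 and 0 passed, and their median change in the called direction was 0.06 log2 against a median of 0.45 for the called probe sets. The further probe set read 0.02 for Gria3, 0.06 for Khsrp, 0.14 for Kif1a, 0.24 for Hpcal4, -0.08 for Kcnip4, -0.08 for Eif3a and 0.00 for Zrsr2-ps1, and the further ones of Ubxn4 read -0.03 and -0.01. Among the 48, 23 had no gene name, or 47.9% against 28.4% of all probe sets tested (Fisher's exact test, p = 0.00566). This test treats probe sets as independent, and those called higher varied together, so its p value may be too small. Within single runs 0 probe sets passed, with 1744, 2117, 702 and 1079 at an unadjusted p under 0.05 in runs 1 to 4. The 48 had the direction of the block fit in 48, 48, 48 and 44 cases, but they were chosen on these same arrays, and of all probe sets tested 69.4%, 82.9%, 66.8% and 75.3% had it too. The count ranged from 10 to 462 when single arrays were left out, and Eif3a was at 4.91 in 1 water array, below the other 5 arrays of its group, the nearest of which was at 6.64.

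**Figure D1:**
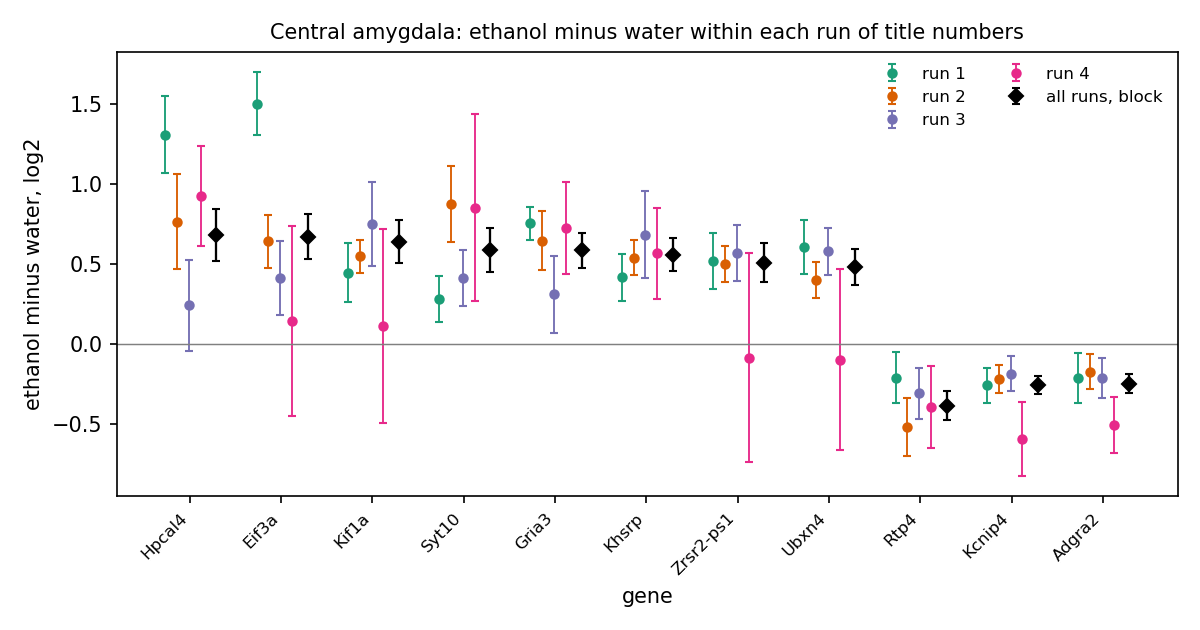
Ethanol minus water differences (log2, vertical axis) of 11 named CeA genes (horizontal axis) within each of the 4 runs and with all runs as a block. Points are estimates and bars are SE. Gria3 differed by 0.75, 0.65, 0.31 and 0.72 in runs 1 to 4, and Rtp4 by -0.21, -0.52, -0.31 and -0.39. The run 4 values compare 2 arrays with 2 at 6 h, 3 of them low-correlation arrays.

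Among the fixed lists, genes of oxidative phosphorylation tended lower in the CeA of ethanol rats: 47 of 53 measured members were below 0, with a median of -0.05, as for Uqcrc2 at -0.12 ± 0.05 and Ndufs8 at -0.15 ± 0.06. Camera called the list lower (adjusted p = 0.00109), and the call was lost at an adjusted p = 0.715 with an estimated correlation. Adjusted over the list alone 0 members passed, and 0 over all genes. Microglia markers had 10 of 11 members lower (median -0.12, Aif1 -0.23 ± 0.12), and meningeal fibroblast markers 7 of 7 (median -0.13, Igfbp2 -0.21 ± 0.10). Kinase and plasticity genes were higher in 19 of 26 (Creb1 0.16 ± 0.06, Prkca 0.14 ± 0.06), chromatin-modifying enzymes in 17 of 24, and medium spiny neuron and dopamine genes, which mark striatal projection neurons, in 15 of 18 (median 0.08, Penk 0.23 ± 0.14). These 5 lists each had a camera adjusted p = 0.0461, and adjusted p = 0.698 with an estimated correlation, or 0.715 for the last. Members of these lists passed neither adjusted over the list alone nor over all genes. Without the 4 low-correlation arrays camera called 1 list in place of 6.

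GABA genes did not pass as a list (camera adjusted p = 0.0588, adjusted p = 0.698 with an estimated correlation). Of 14 members, 4 passed adjusted over the list alone, which leaves the other lists unadjusted, and 0 over all genes. Gad2, which makes GABA, was at 0.36 ± 0.11 (p adjusted over the list alone 0.0233), the receptor subunits Gabrg1 at 0.32 ± 0.10 (0.0233) and Gabra2 at 0.42 ± 0.16 (0.0425), and Gabrb2 at -0.21 ± 0.08 (0.0425). Adjusted in the same way, 1 chaperone passed, Dnajb1 at 0.13 ± 0.04 (0.0405), and 1 gene of endocannabinoid breakdown, Mgll at 0.23 ± 0.06 (0.00659). With the run block Gabrg1 read 0.35 ± 0.07 (1.5e-04 over the list alone), Gad2 0.38 ± 0.09 (0.00118), Gabra2 0.47 ± 0.12 (0.00118) and the AMPA receptor subunit Gria1 0.40 ± 0.11 (0.0193), and 0 of these passed over all genes. Camera then called 8 lists, oxidative phosphorylation first (adjusted p = 1.9e-04, 48 of 53 lower, adjusted p = 0.615 with an estimated correlation) and GABA genes among them (adjusted p = 0.0154, adjusted p = 0.424 with an estimated correlation). No list held with an estimated correlation or with fry. In the fit without the block, cholesterol synthesis genes had a camera direction of higher with a median and mean below 0, and thalamic, hypothalamic and pallidal markers had a median of 0.06 and a mean of -0.01. The other lists tested had camera adjusted p values of 0.0524 to 0.948.

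At single times in the CeA, the question was how the ethanol effect stood 1, 6 and 24 h after the last session. At 1 h the smallest p values were those of Msl1 (1376028_at, 0.76 ± 0.17), Smarce1 (1378203_at, 0.82 ± 0.18), a subunit of a chromatin remodelling complex, Khsrp (0.79 ± 0.19), and Odc1 (1370163_at, 0.32 ± 0.08), the ornithine decarboxylase of polyamine synthesis. Further probe sets read 0.12 and 0.16 for Msl1, 0.07 and -0.00 for Smarce1 and 0.06 for Khsrp. At 6 h they were Adgra2 (-0.51 ± 0.12), Wfdc1 (1387873_at, -0.64 ± 0.17), Herc1 (0.69 ± 0.19) and Kif1a (1.03 ± 0.28). At 24 h they were Chst8 (1381897_at, -0.32 ± 0.10), Uqcc6 (1382763_at, 0.74 ± 0.24), Rtp4 (-0.46 ± 0.16) and Mdh1 (1372790_at, -0.17 ± 0.06). None of these genes passed. With limma 0 probe sets passed at each time, the smallest adjusted p was 0.337, 0.571 and 1.00, and 1012, 1531 and 122 probe sets had an unadjusted p under 0.05. The ethanol by time interaction also passed 0 probe sets, with 250 at an unadjusted p under 0.05 (smallest adjusted p 0.979). Its smallest p values belonged to Sipa1l3 (1377690_at, 0.57 ± 0.16 for 6 h minus 1 h), Klhl36 (1398453_at, -0.42 ± 0.11), Dlst (1370879_at, -0.47 ± 0.13) and Fen1 (1367983_at, -0.60 ± 0.17). The run block also gave 0 for each of these tests.

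At 6 h, oxidative phosphorylation genes of the CeA were lower in 52 of 53 (median -0.17, camera adjusted p = 3.7e-11, adjusted p = 0.402 with an estimated correlation). All 13 oligodendrocyte markers were lower (median -0.43, Mag -0.71 ± 0.35), as were all 11 microglia markers (median -0.23, C1qc -0.54 ± 0.18, p adjusted over the list alone 0.0397). Camera gave these lists adjusted p values of 0.00871 and 0.00242, and adjusted p = 0.558 and 0.402 with an estimated correlation. Immediate early genes, which respond to neuronal activity, were higher in 13 of 18 (Fosb 1.13 ± 0.43, Egr2 1.48 ± 0.65, Fos 0.59 ± 0.27, each 0.168 over the list alone), and neuropeptide genes in 21 of 26. Their camera adjusted p values were 4.39e-04 and 3.6e-04, each with adjusted p = 0.402 with an estimated correlation, and 0 of the 11 lists called at 6 h held with it. In the interaction of 6 h minus 1 h, camera called 9 lists, each with adjusted p = 0.473 with an estimated correlation, and 3 with the run block. Medium spiny neuron and dopamine genes were higher in 18 of 18 at 24 h (median 0.21, adjusted p = 2e-04, adjusted p = 0.919 with an estimated correlation). Camera called 0 lists at 1 h and 3 at 24 h, and with the run block 3, 5 and 3 lists at the 3 times. The water group at 6 h held 5 arrays, 2 of which were among the low-correlation arrays.

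In the NAc shell, the same comparison over the mean of the 3 times (31 against 17 arrays) gave its smallest p values for Snd1 (1367790_at) at 0.17 ± 0.04, Rtp4 at -0.24 ± 0.05, the proton pump subunit Atp6v0c (1398755_at) at 0.26 ± 0.06, and Uqcrc1 (1388301_at), a core subunit of respiratory complex III, at 0.23 ± 0.05. None passed (adjusted p = 0.200 each). Limma passed 0 of 18625 probe sets, with 2061 at an unadjusted p under 0.05, 1257 higher and 804 lower. Atp6v0c was at 12.01 in 1 water array at 1 h, below the other 6 arrays of its group, the nearest of which was at 12.62.

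Oxidative phosphorylation genes tended higher in the NAc shell of ethanol rats: 54 of 54 members were above 0 (median 0.10). Camera called the list (adjusted p = 1.63e-12), but with adjusted p = 0.703 with an estimated correlation and a fry adjusted p of 0.0928. Adjusted over the list alone 4 passed, Uqcrc1 (0.00387), Ndufs3 at 0.16 ± 0.04 (0.0195), Atp5pf at 0.15 ± 0.05 (0.0366) and Ndufb7 at 0.20 ± 0.06 (0.0427), and 0 passed over all genes. Inflammatory and innate immune genes were lower in 9 of 10 (median -0.07, Irf7 -0.13 ± 0.06, Nfkb1 -0.09 ± 0.04, Rela -0.10 ± 0.05), with a camera adjusted p = 0.0246, adjusted p = 0.0595 with an estimated correlation, and a fry adjusted p of 0.00499. Chaperones were higher in 21 of 24 (Ddit3 0.31 ± 0.11, Manf 0.14 ± 0.05, camera adjusted p = 0.0327) and synaptic vesicle genes in 18 of 20 (Syt5 0.22 ± 0.05, Syn1 0.17 ± 0.07, camera adjusted p = 0.0429), both with adjusted p = 0.766 with an estimated correlation. Without the 5 low-correlation arrays camera called 2 lists in place of 4. Adjusted over the list alone, Syt5 passed (0.00374), as did Hdac11 at 0.16 ± 0.04 (0.00847), the endothelial receptor Kdr at -0.18 (0.0229), the sterol enzyme Mvd at 0.19 (0.0337) and the astrocyte enzyme Aldoc at 0.19 (0.0352), and 0 of these passed over all genes. The test, the median and the mean differed in sign for neuropeptide genes (camera lower, median 0.04, mean 0.01), meningeal fibroblast markers (camera lower, median -0.02, mean 0.02) and cortical neuron markers (camera higher, median -0.01).

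By time, 0 probe sets of the NAc shell passed in limma at 1, 6 or 24 h, with 351, 975 and 696 at an unadjusted p under 0.05, and 0 passed for the interaction, with 161. The smallest p values at 1 h belonged to Zfp12 (1380554_at, -0.27 ± 0.08), Hhex (1387270_at, -0.36 ± 0.11), Igdcc3 (1382825_at, -0.28 ± 0.09) and Prpf40b (1377010_at, 0.24 ± 0.08). At 6 h they belonged to Banf1 (1367820_at, 0.30 ± 0.06, adjusted p = 0.284), Rnf145 (1384725_at, -0.45 ± 0.11), Rtp4 (-0.37 ± 0.09) and Tnnc1 (1371354_at, 0.35 ± 0.09). At 24 h they belonged to Snd1 (0.31 ± 0.06, adjusted p = 0.186), the neuronal kinesin Kif5c (1396154_at, 0.72 ± 0.18), Gorasp2 (1370325_at, 0.32 ± 0.09) and Mrto4 (1372043_at, 0.25 ± 0.07). Further probe sets read -0.05 for Rnf145, 0.16 and 0.24 for Kif5c and 0.03 for Mrto4. For the interaction they belonged to Mrto4, Kcnc4 (1391369_at), Gorasp2 and Ndufaf7 (1393274_at). Oxidative phosphorylation genes were higher in 45, 54 and 54 of 54 members at 1, 6 and 24 h (camera adjusted p = 0.0292, 2.03e-11 and 1.43e-09), with adjusted p = 0.931, 0.563 and 0.775 with an estimated correlation. Camera called 2, 5 and 3 lists at these times, and 0 held with an estimated correlation.

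**Figure D2:**
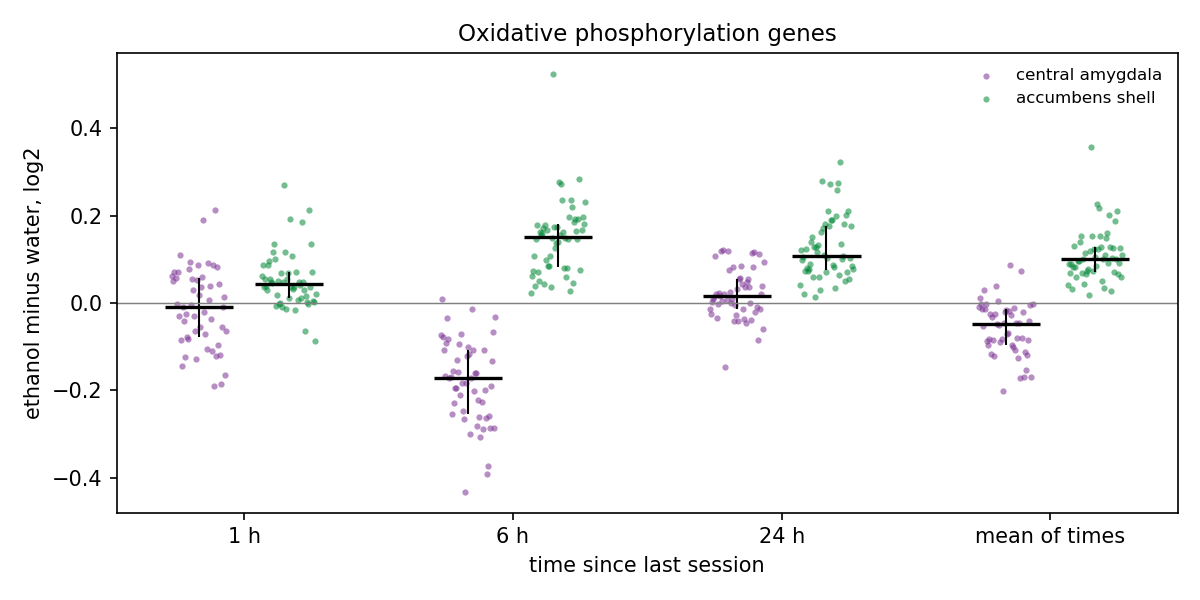
Ethanol minus water difference (log2, vertical axis) of each oxidative phosphorylation gene at 1, 6 and 24 h and over the mean of the times, in the CeA (purple) and the NAc shell (green); points are genes, lines are medians and bars are quartiles. Medians were -0.01, -0.17 and 0.02 in the CeA and 0.04, 0.15 and 0.11 in the NAc shell at the 3 times.

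Ethanol effects of the 2 regions were compared directly in 1 fit of all 96 arrays, to ask where drinking acts differently. Neither this fit nor its list tests and redraws held a block for the CeA runs. Oxidative phosphorylation genes had a lower ethanol effect in the CeA than in the NAc shell in 54 of 54 members (median -0.14). Camera called this difference (adjusted p = 7.21e-15), with adjusted p = 0.802 with an estimated correlation, and fry did not. Adjusted over the list alone Uqcrc1 passed (-0.31 ± 0.07, 0.00396), and 0 members passed over all genes. Microglia markers differed in the same direction in 10 of 10 (median -0.13, Aif1 -0.39 ± 0.15, C1qa -0.29 ± 0.11, camera adjusted p = 0.0402, adjusted p = 0.878 with an estimated correlation). Limma passed 1 probe set, 1381244_at, which has no gene name and was higher by 0.48 ± 0.09 in the CeA effect (adjusted p = 0.0373), and 1719 had an unadjusted p under 0.05. Next came Khsrp (0.59 ± 0.14, adjusted p = 0.253), Uqcrc1 (adjusted p = 0.347), the citrate synthase Cs (1369967_at, -0.26 ± 0.07) and the neurofilament Nefl (1370058_at, -0.38 ± 0.10), which did not pass (adjusted p = 0.430 each for the last pair). The call of 1381244_at ended with the filter at the 60th percentile and after repeated quantile normalization. Of the 96 fits that left out 1 array, 63 passed some probe set, which need not be this one, and the rest passed none.

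Across 17572 probe sets, ethanol effects in the CeA and the NAc shell had a Pearson r of 0.04 and a Spearman rho of -0.02. Genes are not independent replicates, and redrawn group labels gave r of -0.56 to 0.42, with 85 of 99 redraws as far from 0. At 1, 6 and 24 h r between the regions was 0.154, -0.123 and 0.175, with 49, 46 and 38 of 99 redraws as far from 0. Between times within a region r was 0.0828 to 0.373 in the CeA and 0.234 to 0.444 in the NAc shell. For the highest, 6 h with 24 h in the NAc shell, 10 of 99 redraws were as far from 0. These 10 correlations form 1 family, and none was adjusted, since none was beyond its redraws.

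In the CeA of ethanol rats (11, 10 and 10 arrays), the clock repressor Nr1d1 (1370816_at) fell by 0.48 ± 0.08 log2 from 1 h to 6 h (adjusted p = 0.00145) and was 0.02 from its 1 h level at 24 h. Its relative Nr1d2 (1390430_at) fell by 0.32 ± 0.06 (adjusted p = 0.00263). The glucocorticoid-induced kinase Sgk1 (1367802_at) fell by 0.73 ± 0.18 and stood 0.39 ± 0.18 above its 1 h level at 24 h (adjusted p = 0.00380). The transcription factor Klf2 (1376569_at) fell by 0.46 ± 0.12 (adjusted p = 0.0166), while Mmp14 (1367860_a_at), a membrane-bound metalloprotease, rose by 0.36 ± 0.07 (adjusted p = 0.0196). Klhdc7a (1385729_at) rose by 0.59 ± 0.13 (adjusted p = 0.0397) and Aifm3 (1374363_at) by 0.19 ± 0.06 (adjusted p = 0.0470). In all 10 arrays at 6 h these genes lay on the stated side of the 1 h mean, except Aifm3 with 9 of 10. Adjusted p values of single genes, here and below, test 6 h and 24 h against 1 h together. They do not belong to the 6 h change alone.

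In limma 11 probe sets passed for time in CeA ethanol rats and 0 in CeA water rats, where 618 had an unadjusted p under 0.05. The ethanol by time interaction passed 0, so the time courses are not shown to differ. Water rats gave -0.36 ± 0.12 for Nr1d1 (adjusted p = 0.0614), 0.63 ± 0.18 for Klhdc7a (adjusted p = 0.0753), -0.15 ± 0.09 for Ppih (1394554_at, 0.27 ± 0.08 at 24 h, adjusted p = 0.258) and 0.24 ± 0.07 for the chaperone Hspa5 (1370283_at, adjusted p = 0.258), none of which passed. Of the 11 probe sets, 4 had no gene name, and 1 of these, 1390223_at, fell by 0.75 ± 0.09 (adjusted p = 1.66e-06). A further probe set read -0.16 for Nr1d2 and 0.03 for Klf2. With the run block 18 passed. Without the 4 low-correlation arrays 8 passed, and Klf2, Klhdc7a and Aifm3 did not. Over all settings Aifm3 lost its call in 6 of 12, Klhdc7a in 3 of 11 and Klf2 in 2 of 12.

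Clock genes fell as a list from 1 h to 6 h in CeA ethanol rats: 14 of 18 members were lower (median -0.14), with a camera adjusted p = 4.18e-09, adjusted p = 0.00404 with an estimated correlation, and a fry adjusted p of 0.0145. For this contrast 6 members passed adjusted over the list alone and 2 over all genes. Beside Nr1d1 and Nr1d2, the clock output gene Dbp was at -0.52 ± 0.16, Bhlhe41 at -0.15 ± 0.04, Per1 at -0.31 ± 0.11 and Per3 at -0.36 ± 0.11, with p adjusted over the list alone, for both times jointly, of 0.00189, 0.00180, 0.00329 and 0.00480. Bmal1, which Nr1d1 represses, was at 0.25 ± 0.13 (0.265). Glucocorticoid-responsive genes fell in 13 of 15 (median -0.26), with a camera adjusted p = 4.18e-09, adjusted p = 0.0365 with an estimated correlation, and a fry adjusted p of 0.125. For this contrast 5 members passed adjusted over the list alone and 0 over all genes, and the joint values were 0.00107 for Pdk4 at -0.88 ± 0.31, 0.0118 for Nfkbia at -0.40 ± 0.13 and 0.0251 for Klf9 at -0.30 ± 0.10. In water rats 8 of 15 members of this list were above 0, and the interaction of its ethanol effect with time, 6 h minus 1 h, had a camera adjusted p = 0.0636. With the run block the clock and glucocorticoid lists of ethanol rats had adjusted p = 0.00200 and 0.0641 with an estimated correlation. Camera also called chaperones higher (18 of 24, adjusted p = 3.58e-05, adjusted p = 0.350 with an estimated correlation), kinase and plasticity genes higher (adjusted p = 0.0442, 0.867) and oligodendrocyte markers lower (13 of 13, median -0.16, adjusted p = 0.0442, 0.897). In water rats camera called 13 lists and 0 held with an estimated correlation, with clock genes at adjusted p = 0.0911. With the run block it called 7, and clock genes held at adjusted p = 0.0465 with an estimated correlation. Without the block, oligodendrocyte markers were higher in 13 of 13 (median 0.38, adjusted p = 0.0160, adjusted p = 0.619 with an estimated correlation).

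In the NAc shell of ethanol rats (10, 10 and 11 arrays), Sgk1 fell by 0.62 ± 0.13 from 1 h to 6 h and was 0.31 above its 1 h level at 24 h (adjusted p = 2.07e-04). Pdk4 (1378074_at), a kinase that restrains pyruvate oxidation, fell by 0.71 ± 0.22 and was 0.49 above at 24 h (adjusted p = 0.0204). The phosphatase Mtmr2 (1371543_at) fell by 0.25 ± 0.06 (adjusted p = 0.0233). Each lay below its 1 h mean in 10 of 10 arrays at 6 h. The adjusted p values are again for both times jointly. In water rats the smallest p values belonged to the synaptic scaffold gene Homer1 (1370997_at) at -1.76 ± 0.42, Id1 (1387028_a_at) at -0.58 ± 0.14, Snd1 at -0.29 ± 0.07 for 24 h, and Sgms1 (1384106_at) at -0.38 ± 0.10 for 24 h, which did not pass. Limma passed 7 probe sets in ethanol rats, 4 of them without a gene name, and 0 in water rats, where 678 had an unadjusted p under 0.05, and the interaction passed 0. Sgk1 was at 11.01 in 1 ethanol array at 6 h, below the nearest other array of its group at 11.52. The count was 2 without the 5 low-correlation arrays. Mtmr2 lost its call in 3 of 9 settings and Pdk4 in 1 of 9.

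Glucocorticoid-responsive genes of the NAc shell were lower at 6 h in 13 of 16 (camera adjusted p = 1.45e-06, adjusted p = 0.0850 with an estimated correlation, fry 0.0179). For this contrast 7 members passed adjusted over the list alone and 0 over all genes, and Nfkbia was at -0.37 ± 0.11 and Ddit4 at -0.51 ± 0.17 (joint values 2.61e-04 and 0.00159). Clock genes were lower in 12 of 17 (camera adjusted p = 0.00102, adjusted p = 0.344 with an estimated correlation), and 4 passed adjusted over the list alone against 0 over all genes. Dbp was at -0.36 ± 0.09 and Nr1d1 at -0.28 ± 0.09 (joint value 0.00355 each), and Nr1d2 at -0.22 ± 0.07 (0.00454). Medium spiny neuron and dopamine genes were lower in 18 of 18 (adjusted p = 0.00676, 0.756 with an estimated correlation), and immediate early genes in 15 of 18 (Klf4 -0.62 ± 0.18, adjusted p = 0.0118, 0.756 with an estimated correlation). At 24 h against 1 h camera called 1 list in CeA ethanol rats, cholesterol synthesis genes, lower (adjusted p = 0.0186, 0.970 with an estimated correlation). In NAc shell ethanol rats it called oxidative phosphorylation genes, higher (adjusted p = 0.00868, 0.678 with an estimated correlation), and glucocorticoid-responsive genes, higher (adjusted p = 0.0446, also 0.678 with an estimated correlation).

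**Figure D3:**
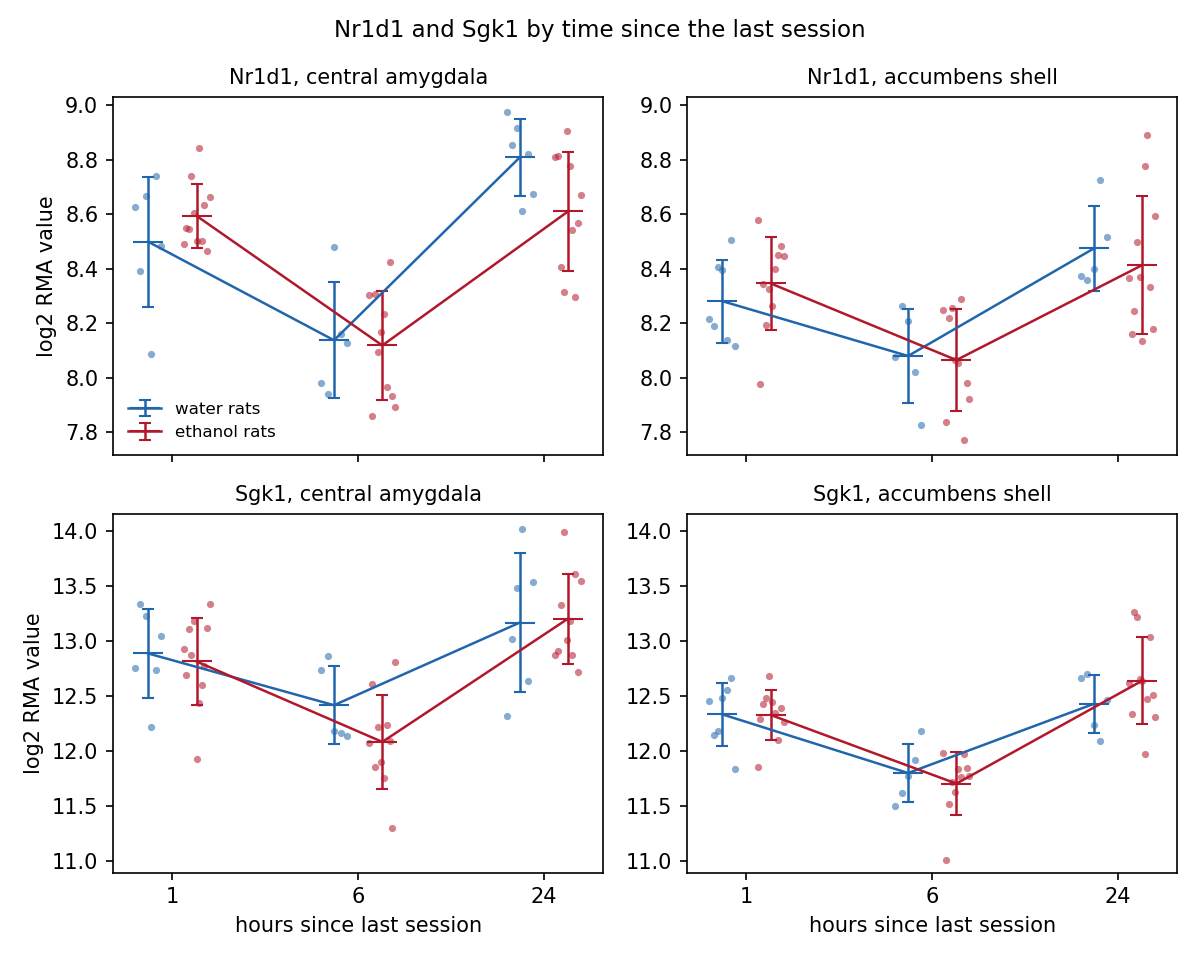
Log2 values of Nr1d1 and Sgk1 (vertical axis) by hours since the last session (horizontal axis) in both regions, ethanol rats in red and water rats in blue; points are arrays, and lines and bars are mean and SD. In CeA ethanol rats Nr1d1 averaged 8.59, 8.12 and 8.61 and Sgk1 12.82, 12.09 and 13.21 at 1, 6 and 24 h.

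Averaged over both treatments, a comparison added after the data were seen, the 6 h minus 1 h change in the CeA was -0.42 ± 0.07 for Nr1d1 (adjusted p = 6.98e-06), -0.25 ± 0.05 for Nr1d2 (adjusted p = 0.00128), -0.35 ± 0.09 for the clock gene Per2 (1368303_at, adjusted p = 0.00998; a further probe set read 0.04) and -0.60 ± 0.16 for Sgk1 (adjusted p = 0.00444). Higher at 6 h were Klhdc7a at 0.61 ± 0.11, Aifm3 at 0.23 ± 0.05 and Hspa5, the main chaperone of the endoplasmic reticulum, at 0.19 ± 0.04 (adjusted p = 0.00212), and Ppih was at -0.17 ± 0.05 (adjusted p = 0.00444; a further probe set read 0.07). Nr1d1, Klhdc7a, Nr1d2, Hspa5 and Sgk1 showed these directions in 15 of 15 arrays, Aifm3 in 14, Ppih in 13 and Per2 in 12. Their adjusted p values test both times jointly, and Ppih stood 0.15 ± 0.05 above its 1 h level at 24 h. Chaperones rose as a list (23 of 24, adjusted p = 5.4e-12, adjusted p = 0.0220 with an estimated correlation, fry 0.0145), with Sdf2l1 at 0.32 ± 0.09, and clock genes fell (adjusted p = 5.48e-04 with an estimated correlation, fry 0.00305). Limma passed 31 probe sets in the CeA, 33 with the run block and 5 without the 4 low-correlation arrays, where Nr1d1 and Klhdc7a passed and the other named genes did not.

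This average passed 15 probe sets in the NAc shell. Its adjusted p values are also for both times jointly, while the changes given are 6 h minus 1 h. Homer1 was lower by -1.45 ± 0.27 (adjusted p = 0.00938), with 3 further probe sets at -0.73 to -0.17, Sgk1 by -0.58 ± 0.11 (adjusted p = 3.83e-04), and Pdk4 by -0.70 ± 0.18 (adjusted p = 0.0309). Klf2 was at -0.58 ± 0.12 (adjusted p = 0.0390; a further probe set read 0.03), Stk17b (1373164_at) at -0.28 ± 0.08 (adjusted p = 0.0390), Tiparp (1374446_at) at -0.30 ± 0.09, Mtmr2 at -0.21 ± 0.05 and Nr1d1 at -0.24 ± 0.07 (adjusted p = 0.0435). Homer1, Sgk1, Pdk4, Mtmr2 and Nr1d1 were lower in 15 of 15 arrays, Stk17b and Klf2 in 14 and Tiparp in 13. The call of Nr1d1 was lost in 5 of 8 settings (highest adjusted p 0.158), those of Mtmr2 and Tiparp in 3 of 9 each (0.184 and 0.0975), those of Pdk4 and Klf2 in 2 of 9 each (0.120 and 0.142) and that of Stk17b in 1 of 9 (0.0510). Homer1 and Sgk1 passed in all 9, which do not include the fits without single arrays. Without water 6 h replicate 27 the count was 1, so Homer1 and Sgk1 did not both pass there. Without the 5 low-correlation arrays 6 probe sets passed, and single arrays moved the count between 1 and 21.

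Water rats gave the baseline difference of the regions (17 against 17 arrays), in which genes of striatal identity stood lower in the CeA. Drd1 (1368479_at), the D1 dopamine receptor, was lower by -2.90 ± 0.17 log2, Rgs9 (1368500_a_at), a brake on dopamine receptor signalling, by -2.95 ± 0.15, the peptide precursor Cartpt (1368585_at) by -2.98 ± 0.23, and the retinoid genes Rarb (1376755_at) and Stra6 (1385475_a_at) by -2.95 ± 0.13 and -2.85 ± 0.11. Nexn (1370697_a_at) was at -2.86 ± 0.20. Higher in the CeA were the retinoic acid-degrading enzyme Cyp26b1 (1384392_at) by 3.96 ± 0.17, the nuclear receptor Nr2f2 (1389554_at) by 3.03 ± 0.15, the neurotrophin receptor Ngfr (1368148_at) by 2.95 ± 0.31, Setd5 (1391170_at) by 3.65 ± 0.15, Pex5l (1370833_at) by 3.13 ± 0.17 and Herc1 by 3.08 ± 0.12. All 17 CeA arrays lay beyond every NAc shell array for these genes, except Ngfr with 16 of 17. Further probe sets had another sign or size for Setd5 (-0.79 and 0.55), Pex5l (0.48) and Cyp26b1 (0.74), and the same sign for Drd1 (-2.63), Nexn (-2.58) and Stra6 (-1.47 and -1.45).

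All 18 medium spiny neuron and dopamine genes were lower in the CeA and passed (median -1.95, camera adjusted p = 2.33e-10, adjusted p = 0.883 with an estimated correlation, fry 1.74e-24). Cholesterol synthesis genes were higher in 16 of 18 (median 0.45) and oligodendrocyte markers in 13 of 13, 12 of which passed (median 0.98), with camera adjusted p = 0.00738 and 0.0174, and adjusted p = 0.883 with an estimated correlation for both. Limma passed 13985 of 18625 probe sets, of which 6728 were higher and 7257 lower in the CeA. The regions look to have been normalized separately, and their Gapdh end differences stood apart, so small differences in this count cannot be told from processing.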

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

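In this part, the tests of RNA integrity, of shared variation, of microglia and of the water rats' time course were chosen only after the result was seen. The run block with composition covariates and the averaged time courses with their redraws were also chosen then. The redraws of labels for the other comparisons and the prediction for cell composition were set before.

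Dixon's test ran within the 10 groups of at most 10 arrays. For 3 measures of array quality it set an array apart in 3 of 30 tests, all 3 for the median correlation with the others, which is 3 of 10 groups for that measure. For named genes it set an array apart in 9 of 140 tests. Chance flags about 1 in 20 groups. The median correlation was 0.954 for replicate 30 of CeA ethanol at 6 h (nearest other 0.969), 0.977 for replicate 29 of NAc shell water at 6 h (nearest 0.984) and 0.977 for replicate 31 of NAc shell water at 24 h (nearest 0.985). Low values stood at 6.997 for Akap8l (CeA ethanol 6 h, replicate 30, nearest 7.54), 9.88 for Aifm3 (CeA ethanol 6 h, replicate 10, nearest 10.01) and 4.91 for Eif3a (CeA water 24 h, replicate 3, nearest 6.64). NAc shell values stood at 12.01 for Atp6v0c (water 1 h, replicate 22, nearest 12.62) and 11.01 for Sgk1 (ethanol 6 h, replicate 43, nearest 11.52). High values stood at 11.77 for Herc1 (CeA ethanol 6 h, replicate 20, nearest 11.09), 12.59 for Nr1d2 (CeA water 6 h, replicate 13, nearest 12.40), 9.39 for Zrsr2-ps1 (CeA water 1 h, replicate 4, nearest 8.98) and 11.90 for Kcnip4 (CeA water 6 h, replicate 16, nearest 11.37).

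By the test of the difference itself, the ethanol effect was higher in the CeA than in the NAc shell for 1381244_at, by 0.48 log2. For oxidative phosphorylation genes the median difference of the effects was -0.14, and for microglia markers -0.13, both by camera at its preset correlation and neither with an estimated one. Between times, the ethanol effect differed from that at 1 h for 9 CeA lists at 6 h and 2 at 24 h, and for 2 and 1 NAc shell lists, at the preset correlation alone.

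Of the 48 probe sets called for ethanol in the CeA with runs as a block, all 48 still passed with the Gapdh end difference as a covariate. Their median size stayed at 0.42 log2. This end difference was 0.01 higher in ethanol than in water rats of the CeA (permutation p = 0.959), so as a covariate it could change the ethanol estimates little. The covariate fit therefore cannot decide on RNA integrity, and the beta-actin end difference was not used as a covariate. With oligodendrocyte and medium spiny neuron marker means as covariates all 48 passed as well, at a median size of 0.39, among 162 probe sets that passed. How far these marker means differed between treatments was not tested, and a covariate that hardly differs changes the estimates little. This fit therefore cannot decide on cell composition. A shared source of variation between arrays of 1 group stays open: once group and run means were removed, the 43 higher probe sets had a mean pairwise correlation of 0.348, against at most 0.0886 in 999 random lists (one-sided p = 0.001, the smallest they can give). The 43 were also higher in the CeA than in the NAc shell of water rats (median 0.92, 38 of 43 above 0, against at most 0.42 in 9999 random lists), so a feature of the dissection may contribute. Ethanol itself, the biological explanation of the design, stays open with it, and the small changes of the genes' other probe sets bear on both.

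Rtp4 was lower in ethanol rats of both regions, by -0.37 ± 0.10 in the CeA and -0.24 ± 0.05 in the NAc shell, and passed in the CeA with the run block or array weights, and in the NAc shell under no setting tried. Fewer microglia could lower an interferon-induced gene, but the microglia marker mean changed by -0.10 ± 0.06 in the CeA and 0.0387 ± 0.0319 in the NAc shell. The marker mean stood above Rtp4 by 0.27 ± 0.08 and 0.27 ± 0.05. With the run block, where Rtp4 passed, the CeA marker mean was at -0.11 ± 0.05 and stood above Rtp4 by 0.27 ± 0.08. Rtp4 was singled out by its p value, which can enlarge these gaps, so a part of microglia in the CeA stays open. In the NAc shell the marker mean was not lower, which argues against fewer microglia as the whole cause there. An effect of ethanol on interferon-regulated expression was tested on a list of its own, with the other hypotheses.

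Time since the session was called in ethanol rats for 11 probe sets in the CeA and 7 in the NAc shell, among them the clock genes Nr1d1 and Nr1d2 (CeA) and the glucocorticoid-induced Sgk1 (both), all lower at 6 h, but also Mmp14, Klhdc7a and Aifm3, which were higher. With the Gapdh covariate 11 of 11 and 7 of 7 still passed, as they did with marker means as covariates. Whether the Gapdh end difference itself differed between times was not tested, so these fits cannot decide on RNA integrity. A time course shared with water rats, such as time of day, stays open and had the values it needs: in the direction of the ethanol rats, the called probe sets changed by a mean of 0.361 in CeA water rats (0.612 in ethanol rats, one-sided permutation p = 0.0191) and 0.278 in NAc shell water rats (0.442 in ethanol rats, one-sided permutation p = 0.0062). Water rats were taken at the same hours since the session, and the interaction passed 0 probe sets, so a course particular to ethanol rats is not shown. Hours since the session and the hour of the day cannot be told apart, since the labels give no clock hours.

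Labels were redrawn so that each result could be set against 100 splits, the real one included. Chance cannot be excluded for the CeA ethanol results at an unadjusted p under 0.05. Over all times 25 splits gave as many probe sets as the real 1519 (highest other 8239), at 1 h 35 as many as 1012 (5124), at 6 h 29 as many as 1531 (6910), at 24 h 84 as many as 122 (5227), and for the interaction 81 as many as 250 (6716). In the NAc shell it cannot be excluded either, with 8 splits for 2061 over all times (4085), 68 for 351 at 1 h (2702), 43 for 975 at 6 h (3660), 66 for 696 at 24 h (4271) and 98 for 161 for the interaction (2936). The same holds for time in water rats, with 52 splits for 618 in the CeA (3701) and 19 for 678 in the NAc shell (1573), and for the gene lists, with 33 splits for 6 lists in the CeA (18) and 48 for 4 in the NAc shell (14). For the difference of ethanol effects between regions, 7 splits called as many as the real 1 (190).

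By a share of splits under 0.05, not adjusted over the results redrawn, chance alone is unlikely but not excluded for time in ethanol rats. The CeA had 3 splits for 11 probe sets (1836) and the NAc shell 4 for 7 (110). The NAc shell share is close to that limit, 6 of the other splits called some probe set, and the count was 3 without ethanol replicate 44 (6 h) or 60 (24 h), 4 without 46 (6 h) and 2 without the low-correlation arrays. For time averaged over treatments, 1 split, the real one, gave 31 in the CeA and 15 in the NAc shell (highest other 1 in each). This comparison was added after the data were seen, and redraws cannot account for that choice, so chance is not excluded. The NAc shell count also fell to 1, no more than the highest other split, without water 6 h replicate 27. Chance can be excluded for the regions in water rats, 1 split for 13985 (127). The CeA ethanol effect with the run block had 3 splits for 48 (2307), a share that was also not adjusted and does not exclude chance. Of its other splits, 6 called some probe set, and its count fell to 10 without water 6 h replicate 17. Without the block, 25 splits gave as many probe sets as the real labels at an unadjusted p under 0.05. Splits that call several times the real count, as the 1836, 2307, 110 and 190 here and the 8239 for CeA ethanol, point to a structure of the samples. The 1836 and 8239 come from fits without the run block, so the runs could account for them, which was not tested, while the 2307 comes from a fit that holds the runs.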

How the results depend on the processing

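Alternatives chosen only after the data were seen were the run block combined with the Gapdh covariate or weights, fits without the low-correlation arrays, an adjusted p of 0.10 for counts other than ethanol over all times, list tests with a covariate, with the run block or without those arrays, and all settings of the averaged time courses; the rest were planned. Of the named genes under these alternatives, 874 values kept direction and side of the threshold, 73 passed newly, 37 no longer passed and 0 reversed; of the counts and agreements, 686 stayed within 1.5 times and 153 did not. Where no cause is given, the cause was not tested. The number of arrays limits the precision. Title numbers did not pair arrays: the 17 numbers shared by CeA ethanol and water arrays gave correlations of -0.78 to 0.75 (median 0.04, 8 over 0.1), the 3 in the NAc shell -0.46 to -0.18.

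For CeA ethanol against water, 0 probe sets became 74 with array quality weights, 2 with the Gapdh covariate, 2 with the replicate block, 48 with the run block and 2 at an adjusted p of 0.10; at 1 h, 1 with weights and 2 with run block and weights. The 48 of the run block became 112 with the Gapdh covariate and 4308 with weights, both including all 48, and 30 of them were among the 74. At an adjusted p of 0.10 the run block gave 152. CeA time in water rats gave 1 with weights and 2 at an adjusted p of 0.10. CeA time in ethanol rats (11) gave 4 with the 60th percentile filter, which tests fewer probe sets, 27 with weights, 18 with the run block, 21 with block and Gapdh covariate and 102 with block and weights. The CeA average over treatments (31) gave 14 with the 60th percentile filter and 5 without the low-correlation arrays. NAc shell ethanol at 6 h gave 1 with the Gapdh covariate. NAc shell time in ethanol rats (7) gave 4 with the 60th percentile filter, 11 with repeated quantile normalization, 16 at an adjusted p of 0.10 and 2 without the low-correlation arrays, and its average over treatments (15) gave 45 with weights, 26 at an adjusted p of 0.10 and 6 without those arrays. The region difference of the ethanol effect (1) gave 2 with no filter, 0 with the 60th percentile filter, 0 with repeated quantile normalization and 50 with weights. The regions in water rats (13985) gave 25009 with no filter and 9174 with the 60th percentile filter, which follow the number tested. CeA lists (6) fell to 0 with an estimated correlation, 3 with the Gapdh covariate and 1 without the low-correlation arrays; NAc shell lists (4) to 0, 2 and 2.

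Leaving out 1 array gave 0 to 14 for CeA ethanol, 0 to 2 at 1 h, 0 at 6 h, at 24 h and for the interaction, 0 to 2 for CeA time in water rats, 8 to 12 in ethanol rats, 9 to 38 for their average, and 10 to 462 for the run block. In the NAc shell it gave 0 to 1 overall and at 24 h, 0 at 1 h, at 6 h, for the interaction and for time in water rats, 3 to 10 for time in ethanol rats and 1 to 21 for the average. The region difference ranged from 0 to 2 and the regions in water rats from 13824 to 13987. By replicate number, CeA ethanol became 1 without ethanol 1 h 2 or 28, 6 h 3 or 30, 24 h 31 or water 6 h 6; 2 without ethanol 24 h 12, water 1 h 10 or 24 h 15; 10 without water 6 h 16 and 14 without water 24 h 14. CeA ethanol at 1 h became 2 without water 1 h 5, and time in water rats 1 without 24 h 9 and 2 without 1 h 10 or 11 or 6 h 13. The CeA average became 16, 9 and 13 without water 6 h 6, 16 and 17. NAc shell ethanol overall and at 24 h became 1 without water 24 h 34. NAc shell time in ethanol rats became 3 without 6 h 44 or 24 h 60 and 4 without 6 h 46. Its average became 1 without water 6 h 27; 2 without 6 h 25 or 28; 3 without ethanol 6 h 48, water 6 h 26, 24 h 33 or 34; 4 without ethanol 1 h 38 or 41, 6 h 42 or 43, water 1 h 18, 19, 21, 22 or 23; 5 without ethanol 1 h 39, 6 without 1 h 35; 7 without 24 h 55, 59 or 60 or water 24 h 30; 8 without ethanol 6 h 46 or 49 or 24 h 62; and 9 without 1 h 32, 34 or 36, 6 h 44 or 24 h 52. The region difference became 2 without CeA water 24 h 14, and 0 without CeA ethanol 1 h 16, 6 h 9, 10, 19 or 22, 24 h 4, 12, 14 or 23, CeA water 1 h 10 or 11, 6 h 2 or 17, 24 h 3, 8 or 9, NAc shell ethanol 1 h 39, 6 h 43 or 48, 24 h 55, 57, 59 or 60, or NAc shell water 1 h 19, 20 or 24, 6 h 25 to 28, 24 h 30, 32 or 33. The run block count became 24, 29, 28, 23 and 29 without ethanol 1 h 1, 2, 6, 7 and 17; 129, 20, 25, 18 and 26 without 6 h 9, 10, 11, 20 and 29; 18, 19, 20, 25 and 118 without 24 h 4, 14, 15, 23 and 24. Without water 1 h 1, 11 and 12 it became 74, 13 and 15; without 6 h 2, 16 and 17, 14, 87 and 10; and without 24 h 3, 7, 8, 9 and 14, 11, 26, 16, 13 and 462.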

Other observations

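The region comparison of untreated baseline and the list of interferon-regulated genes hold values with no place in the report; the interferon tests were chosen only after the change of Rtp4 was seen, with the list written before it was tested. Neuropeptide genes did not differ as a list between the regions of water rats (camera unadjusted p = 0.690), and 18 of 25 members passed adjusted over the list alone, in both directions, where 13985 of 18625 probe sets passed over all genes. In the CeA, galanin (Gal) was higher by 2.95 ± 0.21 log2, corticotropin-releasing hormone (Crh) by 2.46 ± 0.32 and the nociceptin precursor Pnoc by 1.40 ± 0.17. The somatostatin receptors Sstr1 and Sstr2 were higher by 1.63 and 1.37 and the nociceptin receptor Oprl1 by 1.14. Neuropeptide Y (Npy) was lower in the CeA by -2.76 ± 0.13, tachykinin Tac1 by -2.43, the kappa opioid receptor Oprk1 by -1.04 and the melanocortin receptor Mc4r by -0.85 ± 0.16. The cannabinoid receptor Cnr1 was higher by 1.27 and Adra2a by 1.34, while the serotonin receptor Htr4 was lower by -1.70.

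Among GABA genes, 11 of 13 passed between the regions adjusted over the list alone. Gabrd, a subunit of extrasynaptic receptors, was lower in the CeA by -2.09 ± 0.17, Gabra2 and Gabbr2 were each higher by 0.86, and Gad2 differed by -0.03. The kainate receptor subunit Grik1 was higher by 2.31 ± 0.11 and the astrocyte filament Gfap by 2.21 ± 0.17. Immediate early genes were mostly at lower values in the CeA, 15 of 18 with a median of -0.82 (camera adjusted p = 0.116, adjusted p = 0.883 with an estimated correlation, fry adjusted p = 9.29e-07). Fosb was at -2.33 ± 0.23, Arc at -1.50 ± 0.21 and Nr4a1 at -1.16, and among the 3 higher ones Jun was at 1.04 ± 0.08. The clock genes Bmal1, Per1 and Dbp were at -0.82, -0.78 and -0.86, and Rorb at 1.11.

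The ethanol effect on Mc4r, singled out after its values were seen, was 0.28 ± 0.14 in the CeA and -0.45 ± 0.14 in the NAc shell. Its difference of 0.72 ± 0.20 had a p adjusted over the neuropeptide list alone of 0.0108 and did not pass over all genes. The single regions had values over the list alone of 0.675 and 0.0512.

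Lower Rtp4 in both regions may belong to lower interferon-regulated expression. On a list of 58 interferon-regulated genes without Rtp4, camera with an estimated correlation gave an unadjusted p = 0.301 in the CeA, where 18 of 26 measured members were lower (median -0.07), so the question stays open there. In the NAc shell it gave an unadjusted p = 0.0469, with 17 of 24 lower (median -0.05), a value the hypothesis needs, but adjusted over both regions it was 0.0939. A fixed immune list also holds 6 of the 58, of which B2m alone was measured and had been tested there, and without these 6 the p was 0.239 and 0.0389 (adjusted 0.0778). Isg15 in the CeA and Irf7 in the NAc shell were measured in that immune list but were not among the interferon members tested. The preset correlation gave adjusted p = 0.00657 and 0.00320, and fry 0.169 and 0.0885. Usp18 was at -0.33 ± 0.10 in the CeA and -0.17 ± 0.06 in the NAc shell, while Psmb10 was at 0.01 ± 0.06 and 0.19 ± 0.05.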
